A study of Homo sapiens with 6 samples.

How the data were processed

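Polyadenylated RNA of 6 libraries, 3 from LY19WT and 3 from LY19Y646F, was prepared with a stranded mRNA kit and sequenced from a single end, per the labels' protocols. The groups and the replicate numbers were taken from the sample titles. The labels describe the libraries of a line as biological replicates without saying whether they came from separate cultures, so the p-values measure the spread between these libraries.

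Reads were aligned with STAR 2.5.3a, and Cufflinks 2.2.1 and Cuffdiff 2.2.1 were run on the hg19 build, per the submitters' processing notes. Each library has a deposited table of FPKM per gene, with the 95% confidence interval of Cufflinks and a status per gene, per the file headers. FPKM relates fragments to transcript length and to the total of mapped fragments, so the authors had already scaled each library to its own total. Each table holds loci assembled in that library alone: 47.1% to 51.5% of its rows carry an assembly identifier, and 3189 to 3443 rows name more than 1 gene. A gene can therefore sit in a row of its own in one library and in a merged row in another, which can move its FPKM or leave it listed at 0. Between 20.1% and 26.2% of rows carry no gene name and were not used, and 21 to 30 rows per library have a failed status. The authors' deposited table of the Cuffdiff comparison holds mean FPKM per line and a log2 fold change for 13674 genes. It has no p-value or significance column, so the planned comparison with its significant genes was not possible and only direction and size were compared.

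Depth was estimated from the upper limits of the confidence intervals, since a Cufflinks interval implies a fragment number. That number was whole within a relative tolerance of 0.01 for 60.3% to 63.0% of the rows examined, too few for the reads to be recovered. Large numbers pass a relative tolerance whether whole or not, so this share does not test the fragment numbers. In the rows that passed, the value of a single fragment gave rough relative depths. They were 1.00, 1.10 and 1.06 for LY19WT and 1.06, 1.10 and 1.00 for LY19Y646F. Absolute depth is unknown, so no counting interval or detection limit is given. Precision rests on the spread of 3 libraries per line.

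Rows were joined by gene symbol, not by identifier as planned, because the assembly identifiers differ between libraries. A row counted for a gene when that gene was its only protein-coding name. Genes that shared a row with another protein-coding gene, or had a failed row, in any library were left out, which removed 8768 symbols and left 47205. Gene types came from the GENCODE annotation of a later build, and no coordinate of that build was used. Coordinates are those of the files on hg19, counted from 1. Chromosome Y genes and XIST were left out of all results, because sex-linked levels are not reported here for human samples, so they take no part in judging whether the lines share an origin. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, 10680 in all, 7477 of them protein-coding.

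Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, LY19Y646F minus LY19WT, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Changes on this scale understate the fold of low genes. FPKM are not counts, so no count model was used. The fit was tested on simulated data with 200 changed genes among 10680, drawn from genes with higher mean values. It recovered 44 of 100 2-fold changes and 71 of 100 4-fold changes, with 8 false calls among 123. In the real data 33.2% of tested genes were called, a far larger share, so these recovery rates do not carry over to the comparison of the lines. Gene lists, 29 with 806 symbols, were fixed before the data were examined and drawn from general knowledge, and 782 of the symbols were found in the files. Lists with at least 5 tested members were tested with limma's camera at a preset correlation, with camera at an estimated correlation and with fry. At an estimated correlation camera also rests on fewer degrees of freedom, those of the libraries and not of the genes. Its p can therefore rise without correlated members. Pairs of neighbouring called genes were compared with 10000 shuffles of the calls, a step that gave p = 0.83 and p = 0.74 by permutation on shuffled calls of 10658 genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the joins, exact permutation tests and plots.

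The genes named in the text were chosen by a rule set before the data were examined: EZH2, the 12 largest rises and 12 largest falls among called genes whose libraries do not overlap and whose higher line averages at least 2 FPKM, and up to 4 members per list with the smallest adjusted p, chosen first from the direction with more calls, along with PRDM1, IRF4, BCL6, CDKN1A, CDKN2A, CIITA, MYC and EZH1 where tested. Members called in the other direction can therefore go unnamed even with a smaller adjusted p, so the named members of a list do not show its balance, which the counts give. Immunoglobulin segments, pseudogenes, small RNAs, clone-named loci, XIST and chromosome Y genes were outside the rule. The immunoglobulin rows, LCK, MS4A1, IGLL1 and the runs of neighbouring genes were singled out after their values were seen. Some genes that the rule selects are not reported here.

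Replicate numbers are shared by the lines. Deviations from the line means correlated at 0.27, 0.11 and 0.14 across genes between same-numbered libraries, and at -0.19 to 0.096 between libraries with different numbers. The same-numbered values were all above 0.1, so the numbers were taken to pair the libraries, on this hint from the data alone. The hint is clear for replicate 1 only, since replicates 2 and 3 correlated at 0.096 and 0.053 across numbers. A fit with the replicate number as a block was compared with the unblocked one. Other alternatives were pseudocounts of 0.1 and 0.5 FPKM, no filter, a filter at 2 FPKM, median-ratio and quantile scaling, no variance trend, robust variance, library weights and each library left out in turn. Counting genes alone in their row, counting merged rows for every gene, testing protein-coding genes only and shuffling calls within chromosomes were added after the data were seen.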

Results

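Messenger RNA was sequenced from cultured human cells labelled as 2 lymphoma B cell lines, LY19WT and LY19Y646F. LY19WT is labelled as carrying wild-type EZH2, and LY19Y646F as expressing the mutant EZH2-Y646F constitutively from a CMV promoter. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3, and the Y646F change is recurrent in lymphomas of germinal centre origin. Each line gave 3 libraries described as biological replicates, all from untreated cells, and each library has a table of FPKM per gene. Read totals per library were not given in the sources used here. A rough estimate from the confidence intervals in the tables put the relative depth of the 6 libraries between 1.00 and 1.10. On that estimate depth differed little between the lines. Summed FPKM ranged from 806102 to 1020940. The 10 highest rows held 27.5% of that sum in LY19WT replicate 3 and between 5.71% and 9.38% in the other libraries. Across 10680 tested genes, which are not independent replicates, Pearson's r lay between 0.867 and 0.929 within a line and between 0.733 and 0.773 across the lines.

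The first question was whether the LY19Y646F libraries held more EZH2 RNA, since the mutant is expressed from an added promoter. EZH2 (hg19 chromosome 7, 148504475 to 148581413) measured 60.6, 76.5 and 74.7 FPKM in the 3 LY19WT libraries and 70.2, 80.4 and 93.5 FPKM in the 3 LY19Y646F libraries. The means were 70.6 ± 8.73 and 81.4 ± 11.7 FPKM (SD, n = 3 each). The difference of 0.20 on the log2(FPKM + 1) scale (SE 0.15) had a limma adjusted p of 0.38. The exact two-sided permutation p was 0.40, and 3 libraries against 3 cannot give less than 0.10. By replicate number, a pairing that the data hint at for replicate 1 only, EZH2 was higher in LY19Y646F in 3 of 3 pairs. The blocked limma fit gave an SE of 0.079 and an adjusted p of 0.15. The exact paired sign-flip p was 0.25, the smallest that 3 pairs can give. The tables do not separate introduced from native EZH2 transcripts, nor mutant from wild-type sequence, so the EZH2 level does not check the labels of either line.

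The libraries of the 2 lines differed in their immunoglobulin RNA, a difference that goes with every gene group described below. Rows naming IGKC, the kappa light chain constant region, summed to 4677 ± 342 FPKM in the libraries labelled LY19Y646F and 46.4 ± 7.498 FPKM in those labelled LY19WT (SD, n = 3 each). The heavy chain variable segment IGHV3-23 stood at 5219 ± 1136 FPKM against 0.861 ± 0.729 FPKM (0.441 without LY19WT replicate 3). In the opposite direction, rows naming the lambda segment IGLV1-40 held 374 ± 68.2 FPKM in LY19WT and 0, 0.0803 and 0 FPKM in the 3 LY19Y646F libraries, and rows naming the gamma heavy chain constant genes held 204 ± 172 (106 without LY19WT replicate 1) against 3.64 ± 2.38 FPKM. Rows naming the lambda constant genes held 557 ± 305 against 108 ± 158 FPKM, with 290 FPKM in LY19Y646F replicate 1. MS4A1, which encodes the mature B cell antigen CD20, measured 104 ± 18.5 FPKM in LY19Y646F and 0.0990 ± 0.0369 FPKM in LY19WT. IGLL1, part of the surrogate light chain of precursor B cells, measured 776 ± 746 FPKM in LY19WT (351 FPKM without replicate 1) and 1.28 ± 2.12 FPKM in LY19Y646F. For each of these genes the 3 libraries of a line did not overlap with those of the other. Many of these rows merge several neighbouring genes, so the values describe the row that names the gene, and no test was run on them.

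**Figure D1:**
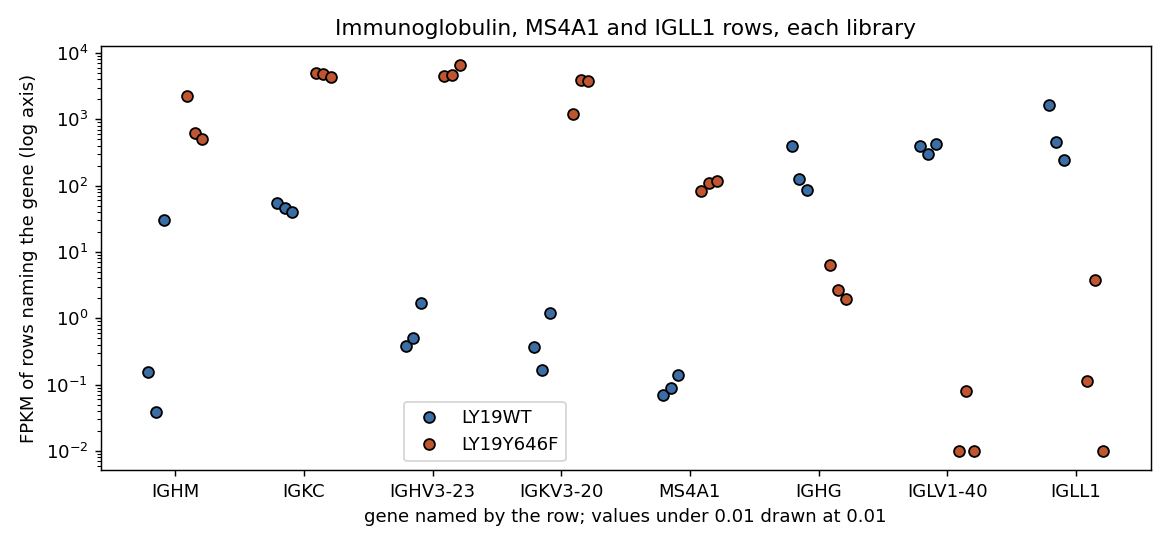
FPKM on a log axis of the rows that name each immunoglobulin gene, MS4A1 or IGLL1, with a point for each of the 3 libraries of LY19WT (blue) and LY19Y646F (orange), values under 0.01 being drawn at 0.01. IGHM, IGKC, IGHV3-23, IGKV3-20 and MS4A1 were higher in all 3 LY19Y646F libraries, and IGHG, IGLV1-40 and IGLL1 in all 3 LY19WT libraries.

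The main comparison asked which genes differed between the lines. Going from the libraries labelled LY19WT to those labelled LY19Y646F, CHI3L2, a chitinase-like protein, rose from 0.656 ± 0.302 to 612 ± 13.3 FPKM (SD, n = 3 each), and IGJ, the joining chain of polymeric immunoglobulin, rose from 0.490 ± 0.221 to 447 ± 83.0 FPKM. IRF8, a transcription factor of B and myeloid cells, rose from 0.234 ± 0.0284 to 196 ± 60.2 FPKM, and MGST1, a microsomal glutathione transferase, from 0.0749 ± 0.130 to 290 ± 110 FPKM. VIM, the intermediate filament vimentin, fell from 414 ± 162 to 0.149 ± 0.0685 FPKM, and the tetraspanin CD9 from 267 ± 26.1 to 0.376 ± 0.0820 FPKM. DNTT, the terminal transferase that adds nucleotides during antigen receptor rearrangement, fell from 120 ± 43.4 to 0.0703 ± 0.0193 FPKM. VPREB1, the other part of the surrogate light chain, fell from 262 ± 128 to 1.08 ± 0.667 FPKM. Limma with Benjamini-Hochberg adjustment called 3546 of the 10680 tested genes at an adjusted p under 0.05, of which 1780 were higher and 1766 lower in LY19Y646F. Of these, 2181 differed at least 2-fold on the log2(FPKM + 1) scale, 1011 higher and 1170 lower. Weighting the libraries raised the count to 5753. The 3 libraries of a line did not overlap with the other line's in 5184 tested genes, or 48.5%, where chance gives 10%.

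**Figure D2:**
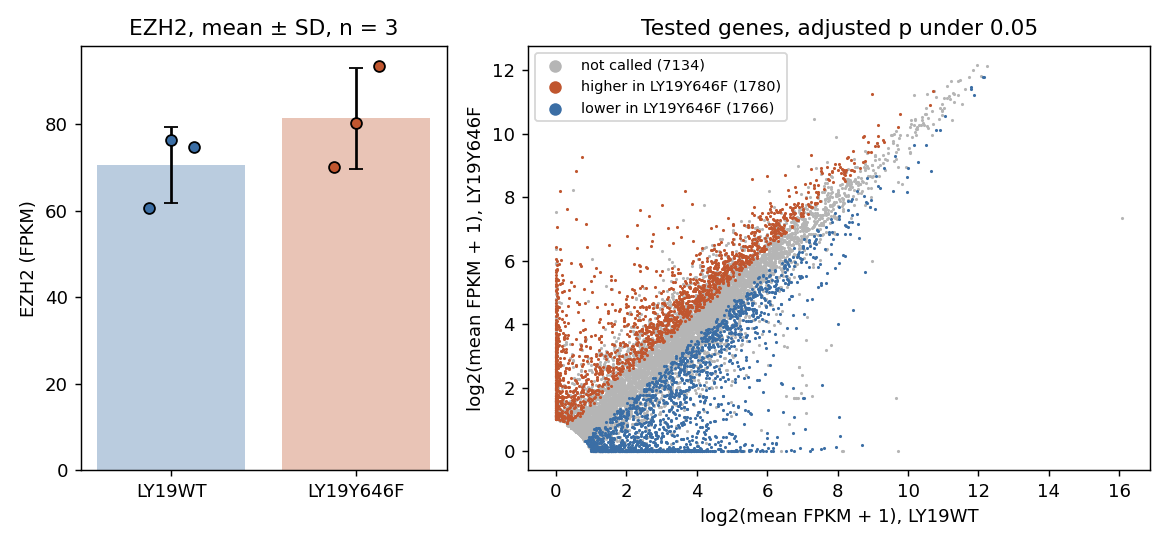
Left, EZH2 in FPKM, with bars at the mean of each line, error bars of 1 SD and a point for each of 3 libraries. Right, log2 of the mean FPKM + 1 of 10680 tested genes in LY19WT (horizontal) and LY19Y646F (vertical), with 1780 genes higher (orange) and 1766 lower (blue) in LY19Y646F at an adjusted p under 0.05.

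The other genes with the largest rises were S100A10, FCRLA, SEL1L3, CPNE5, CYB5A, SHISA9, MGME1 and ECI2, with log2 changes from 5.68 to 7.01. Those with the largest falls were AKAP12, F13A1, IGFBP2, SOCS2, NRN1, GTSF1, IDH2 and S100A13, with log2 changes from -7.83 to -6.13. MGME1 and ECI2 were listed at 0 in each LY19WT library, but the authors' deposited table gives them 32.6 and 29.5 FPKM there against 111.9 and 71.4 FPKM in LY19Y646F. For SHISA9 that authors' deposited table gives 3.55 FPKM in LY19Y646F, where the library tables average 56.6 ± 10.1 FPKM (SD, n = 3). S100A13 was listed at 0 in each LY19Y646F library. A gene listed at 0 can lie in a locus that the assembly joined to others: 294 called genes were listed at 0 throughout a line, and of the 243 that the authors' deposited table holds, 63 have at least 1 FPKM there in that line. For a like comparison, changes in that table were recomputed from its mean FPKM on the log2(FPKM + 1) scale, in place of its own fold change. Among the 2909 called genes in that table, 2855 had the same direction, but of the 1805 called at least 2-fold apart here, 310 were under 2-fold apart or opposite there on that scale. Across the 8282 tested genes in that table, which are not independent, the log2 changes on that scale correlated at a Pearson's r of 0.857.

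Germinal centre genes rose on balance in LY19Y646F. Of 24 tested members, 11 were higher and 4 lower, or 14 and 4 adjusted over the list alone. RGS13 rose from 3.93 ± 0.769 to 138 ± 15.9 FPKM (SD, n = 3 each), GCSAM from 0.596 ± 0.125 to 58.1 ± 8.30 FPKM and LRMP from 46.5 ± 2.41 to 383 ± 5.30 FPKM. BCL6, a transcriptional repressor and master regulator of the germinal centre, rose from 14.6 ± 10.6 to 72.0 ± 48.2 FPKM. By replicate number it measured 9.82, 7.34 and 26.8 FPKM in LY19WT and 45.7, 42.6 and 128 FPKM in LY19Y646F, so replicate 3 was highest in both lines. Its limma adjusted p was 0.047, and 0.074 to 0.14 when any library other than LY19WT replicate 3 was left out. Limma's camera gave the list an adjusted p of 0.021, and an adjusted p of 0.48 with an estimated correlation. That correlation was 0.0143, close to the preset one, so correlated members hardly account for the higher p. The call was lost without LY19Y646F replicate 1 (adjusted p of 0.076), with quantile scaling (0.058), with library weights (0.056) and with genes alone in their row (0.099).

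Genes of B cell identity and receptor signalling were higher for 10 of 22 tested members and lower for 3, or 11 and 3 adjusted over the list alone. BLK, a kinase of the B cell receptor pathway, rose from 0.0151 ± 0.0189 to 28.8 ± 4.80 FPKM (SD, n = 3 each), and CD40 from 0.715 ± 0.305 to 16.7 ± 3.52 FPKM. The lymphoid factor IKZF3 rose from 0.0133 ± 0.0118 to 30.2 ± 7.83 FPKM, although the authors' deposited table lists 3.99 FPKM for it in LY19Y646F. Camera gave an adjusted p of 0.035 and an adjusted p of 0.53 with an estimated correlation of 0.136. The call was lost in the blocked fit (adjusted p of 0.096), without LY19WT replicate 3 (0.073) and without LY19Y646F replicate 1 (0.13). It was also lost with a filter at 2 FPKM (0.12), quantile scaling (0.066), library weights (0.12), protein-coding genes only (0.069) and genes alone in their row (0.37). Plasma cell genes were split, with 3 higher and 4 lower of 10 tested, and the same counts adjusted over the list alone. PRDM1, the repressor that drives plasma cell differentiation, fell from 6.29 ± 0.392 to 0.133 ± 0.0723 FPKM, XBP1 from 155 ± 10.9 to 26.5 ± 2.17 FPKM and SDC1 from 2.55 ± 1.11 to 0.0610 ± 0.0246 FPKM, while IGJ rose as given above. The list's median change of -0.61 and its mean of 0.23 differed in sign, and camera pointed down with an adjusted p of 0.78. The light and heavy chain rows described above moved with the same libraries.

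Interferon response genes fell in LY19Y646F: 18 of 24 tested members were lower and 0 higher, or 19 and 0 adjusted over the list alone. IFIT3 fell from 6.84 ± 0.566 to 0.318 ± 0.0565 FPKM (SD, n = 3 each) and the transcription factor IRF1 from 28.7 ± 4.18 to 3.78 ± 0.802 FPKM. SAMD9L fell from 3.83 ± 0.432 to 0.138 ± 0.0509 FPKM. CMPK2 was listed at 0 in each LY19Y646F library and averaged 4.73 ± 0.375 FPKM in LY19WT. Camera gave an adjusted p of 7.9e-07, and an adjusted p of 0.086 with an estimated correlation. That correlation was -0.0196, below the preset one, so the higher p does not come from correlated members. Genes of MHC class I presentation fell for 4 of 7 tested members and rose for 0, or 5 and 0 adjusted over the list alone. B2M, the light chain of class I molecules, fell from 3723 ± 223 to 2393 ± 90.7 FPKM, the class I transactivator NLRC5 from 15.5 ± 2.82 to 1.33 ± 0.568 FPKM, and the proteasome activators PSME1 and PSME2 fell by 2.08 and 1.26 on the log2 scale. The list's camera adjusted p was 0.024, and an adjusted p of 0.53 with an estimated correlation of 0.297. It was 0.069 without LY19WT replicate 1, 0.060 without LY19Y646F replicate 1, 0.056 with library weights and 0.068 with genes alone in their row. Of 7 tested MHC class II genes 2 were higher and 0 lower, also adjusted over the list alone, and the list did not pass (camera adjusted p of 0.31). HLA-DRA rose from 151 ± 13.7 to 638 ± 71.7 FPKM and HLA-DPA1 from 63.0 ± 6.86 to 405 ± 97.3 FPKM. Their transactivator CIITA measured 2.46 ± 0.243 and 8.40 ± 8.47 FPKM and did not pass, with 18.2 FPKM in LY19Y646F replicate 1 and a log2 difference of 0.38 without it in place of 1.08.

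**Figure D3:**
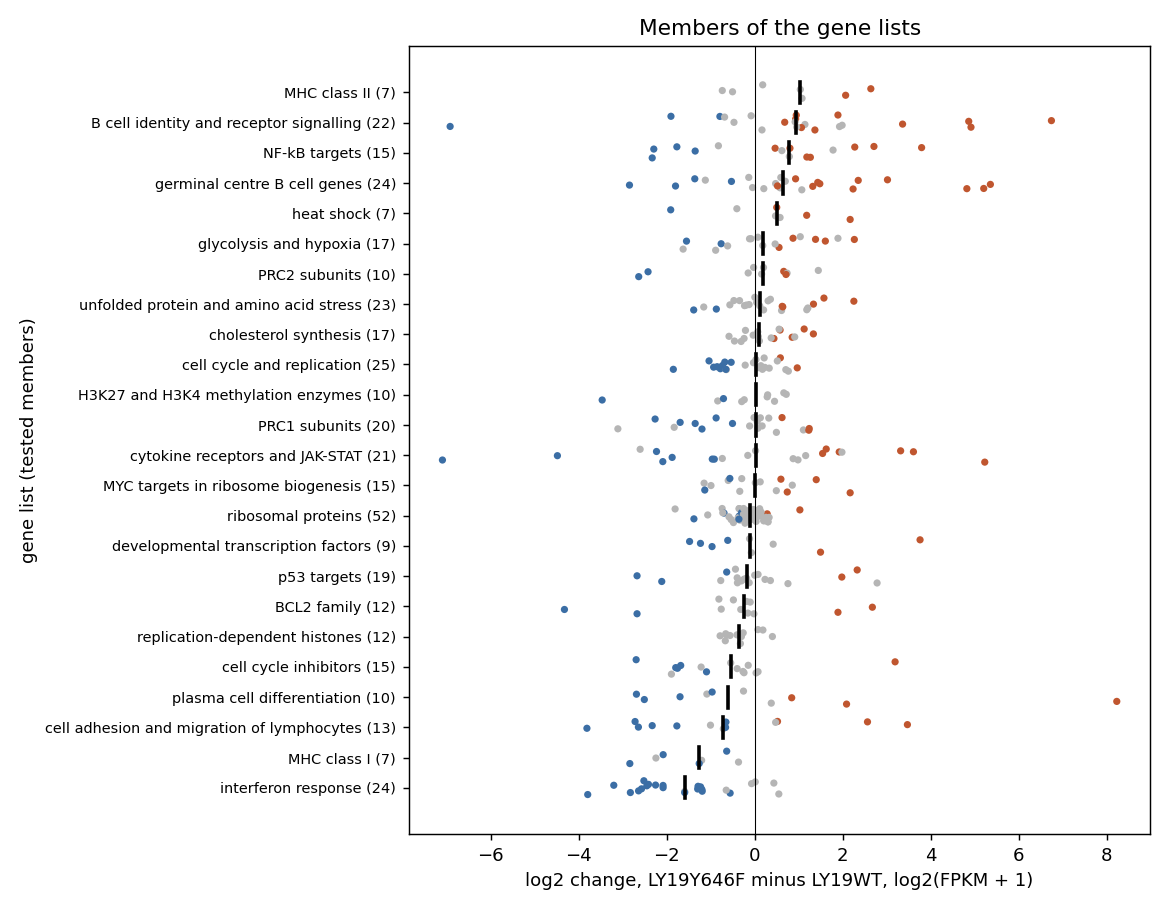
Log2 change per gene, LY19Y646F minus LY19WT on the log2(FPKM + 1) scale, for the members of each gene list with at least 5 tested members, with a black line at the list's median. Orange points rose and blue points fell at an adjusted p under 0.05 and grey points did not pass, as for interferon response, where 18 of 24 members fell.

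Polycomb genes changed in both directions, as did tested genes as a whole. Of all 10680 tested genes 33.2% were called, 1780 higher and 1766 lower, so changes in both directions are not particular to Polycomb genes. Of 10 tested PRC2 subunits 2 rose and 2 fell, also adjusted over the list alone. The histone-binding subunit RBBP4 rose from 194 ± 23.0 to 307 ± 27.5 FPKM (SD, n = 3 each), and JARID2, an accessory subunit that recruits PRC2, fell from 6.22 ± 1.47 to 0.148 ± 0.0662 FPKM. EZH1, the paralog of EZH2, measured 7.54 ± 0.795 and 7.38 ± 0.532 FPKM and did not pass. Of 20 tested PRC1 subunits 3 rose and 6 fell, or 3 and 7 adjusted over the list alone, among them PHC2 (32.5 ± 1.97 to 12.1 ± 0.677 FPKM) and RYBP (7.65 ± 0.813 to 3.71 ± 0.431 FPKM). Enzymes of H3K27 and H3K4 methylation fell for 2 of 10 tested members and rose for 0, also adjusted over the list alone, with KDM5B, a demethylase of H3K4, falling from 10.2 ± 1.09 to 0.00752 ± 0.00333 FPKM. Of 39 HOX genes 2 were tested, since most of the others were below the level for testing or shared rows with other genes. Both fell, HOXB7 from 9.23 ± 2.35 to 0.00977 ± 0.0169 FPKM. Developmental transcription factors rose for 2 and fell for 4 of 9 tested members, also adjusted over the list alone, with WT1 falling from 1.80 ± 0.245 to 0.00244 ± 0.00422 FPKM. Camera adjusted p-values for PRC2, PRC1, the methylation enzymes and the developmental factors were 0.78, 0.72, 0.78 and 0.78. HOX genes were too few for that test here. Without a filter, 6 of 10 members were called lower and 0 higher. Camera then pointed down with an adjusted p of 5.9e-06, and an adjusted p of 0.086 with an estimated correlation of -0.076. With merged rows counted for every gene, 10 of 14 members were called lower and 0 higher. There 5 to 8 values of the members per library repeat that of another member, and of 7 distinct members 5 were lower. Camera pointed down with an adjusted p of 6.8e-06 in that setting, and an adjusted p of 0.35 with an estimated correlation of 0.269. Median and mean differed in sign for PRC2 (0.18 and -0.13), PRC1 (0.02 and -0.38), the methylation enzymes (0.02 and -0.31) and the developmental factors (-0.12 and 0.13), and camera pointed up for PRC2 and down for the others.

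Cell cycle inhibitors fell for 5 of 15 tested members and rose for 1, also adjusted over the list alone. CDKN1B, which encodes p27, fell from 24.98 ± 5.63 to 3.02 ± 0.863 FPKM (SD, n = 3 each), RB1, the retinoblastoma protein, from 83.3 ± 11.4 to 24.0 ± 3.41 FPKM and CDKN2C from 36.7 ± 3.21 to 11.03 ± 3.37 FPKM. CDKN1A measured 21.01 ± 4.50 and 18.7 ± 13.0 FPKM and did not pass. Cell cycle and replication genes rose for 2 and fell for 9 of 25 tested members, also adjusted over the list alone, with CCNB2 falling from 89.2 ± 0.381 to 48.9 ± 0.493 FPKM and TYMS from 445 ± 62.5 to 231 ± 4.12 FPKM. In the BCL2 family 2 of 12 tested members rose and 2 fell, also adjusted over the list alone. BCL2, which blocks apoptosis, fell from 44.4 ± 2.29 to 1.27 ± 0.109 FPKM, and PMAIP1, which promotes it, rose from 21.2 ± 1.61 to 81.6 ± 6.70 FPKM. The other 2 called members also promote apoptosis and moved apart. BMF rose from 0.129 ± 0.114 to 7.83 ± 5.56 FPKM, and BAX fell from 184 ± 43.8 to 36.6 ± 34.7 FPKM (limma adjusted p of 0.028 and 0.030). Targets of p53 rose for 2 and fell for 3 of 19 tested members, also adjusted over the list alone. Among them SESN1 fell from 37.2 ± 2.99 to 8.15 ± 2.87 FPKM, while RRM2B rose from 8.86 ± 0.727 to 48.5 ± 3.94 FPKM. Camera adjusted p-values were 0.22 for the inhibitors, 0.63 for cell cycle genes, 0.72 for the BCL2 family and 0.89 for p53 targets, whose median of -0.18 and mean of 0.01 differed in sign, as did those of the cell cycle genes (0.03 and -0.16), with camera pointing down for both.

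Targets of NF-kB rose for 7 and fell for 4 of 15 tested members, or 9 and 5 adjusted over the list alone. The costimulatory ligand CD86 rose from 0.0636 ± 0.0440 to 13.9 ± 2.39 FPKM (SD, n = 3 each) and CD83 from 9.76 ± 1.29 to 24.7 ± 0.858 FPKM. Among 21 tested cytokine receptors and JAK-STAT genes 6 rose and 7 fell, also adjusted over the list alone, including STAT5A, which fell from 31.0 ± 3.45 to 0.443 ± 0.274 FPKM, and IFNGR1, a receptor chain for interferon gamma, which fell from 78.9 ± 2.34 to 16.1 ± 1.84 FPKM. Genes of lymphocyte adhesion and migration rose for 3 and fell for 7 of 13 tested members, also adjusted over the list alone, with the adhesion ligand CD58 falling from 34.8 ± 3.99 to 1.59 ± 0.685 FPKM and the integrin ITGA4 from 130 ± 25.5 to 19.0 ± 4.36 FPKM. The camera adjusted p-values of these lists were 0.45, 0.89 and 0.22, and the JAK-STAT median of 0.02 and mean of -0.04 differed in sign, with camera pointing down. Most markers of other cell types were below the level for testing. Of the few tested, 3 of 4 for T and NK cells, 2 of 2 for myeloid cells and 1 of 1 for fibroblasts and epithelia fell and 0 rose, with CD247, the zeta chain of the T cell receptor, falling from 28.95 ± 0.795 to 0.477 ± 0.196 FPKM and LYZ, lysozyme, from 11.9 ± 1.63 to 0.156 ± 0.0934 FPKM. The fibroblast and epithelial marker was ACTA2, which was listed at 0 in each LY19Y646F library and has 0.727 FPKM there in the authors' deposited table. Without a filter, the 20 tested T and NK markers had a median change of 0.05 (camera adjusted p of 0.68), the 12 myeloid markers 0.01 (0.72) and the 14 fibroblast and epithelial markers 0.008 (0.82). LCK, a kinase of T cells that shares a row with another gene in part of the libraries and was singled out after its values were seen, stood in rows of 0.323 ± 0.144 FPKM in LY19WT and 140 ± 155 FPKM in LY19Y646F (51.0 FPKM without replicate 1), and was not tested.

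None of the metabolic and housekeeping lists passed camera. Cholesterol synthesis genes rose for 5 of 17 tested members and fell for 0, with SC5D rising from 13.9 ± 1.24 to 31.7 ± 5.39 FPKM (SD, n = 3 each). Glycolysis and hypoxia genes rose for 5 and fell for 2 of 17, with BNIP3 rising from 8.78 ± 1.31 to 46.2 ± 8.40 FPKM. Genes of the unfolded protein and amino acid stress responses rose for 5 and fell for 2 of 23, with TRIB3 rising from 7.06 ± 0.408 to 19.6 ± 4.41 FPKM. Heat shock genes rose for 3 and fell for 1 of 7, with HSPD1 rising from 506 ± 33.4 to 2444 ± 1172 FPKM and the co-chaperone BAG3 falling from 9.69 ± 1.24 to 1.86 ± 0.445 FPKM. Targets of MYC in ribosome biogenesis rose for 4 and fell for 2 of 15, with ODC1 rising from 280.3 ± 25.1 to 470.3 ± 61.2 FPKM. MYC itself is given no value, since unnamed assembled rows cover its locus in part of the libraries. In each of these 5 lists the counts adjusted over the list alone were the same. Ribosomal protein genes rose for 2 and fell for 5 of 52, or 1 and 2 adjusted over the list alone, and replication-dependent histone genes passed in 0 of 12. Camera adjusted p-values were 0.31, 0.40, 0.40, 0.70, 0.85, 0.71 and 0.41 in this order. No transcript of the mitochondrial genome was among the tested genes.

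EZH2 marks broad stretches of chromatin, so the last comparison asked whether neighbouring genes changed together. The interferon-induced genes IFIT2, IFIT3, IFIT1 and IFIT5 on chromosome 10 (91061712 to 91180758) all fell, as did GHDC, STAT5B, STAT5A and STAT3 on chromosome 17 (40340817 to 40540586), while KIAA2018, NAA50, ATP6V1A and GRAMD1C on chromosome 3 (113367232 to 113666357) all rose. These 3 runs of 4 genes were picked as the longest among protein-coding genes after the values were seen. Among 4323 pairs of neighbouring tested genes with starts at most 100 kb apart, 140 pairs fell together where 10000 shuffles of the calls gave a mean of 118 (one-sided permutation p = 0.018). Another 141 pairs rose together where the shuffles gave 120 (permutation p = 0.026). Genes are not replicates, so these p-values describe these libraries. The excess was larger at a limit of 500 kb, with 322 falling pairs against 219 and 295 rising pairs against 223 (permutation p = 0.0001 each, the smallest that the shuffles can give), and among calls of at least 2-fold, with 74 falling pairs against 51.7 (permutation p = 0.001) and 55 rising pairs against 38.8 (permutation p = 0.006). Neither excess within 100 kb held at a limit of 50 kb (permutation p = 0.48 and 0.74) or among protein-coding genes alone (permutation p = 0.27 and 0.67), and the rising excess missed the threshold with calls shuffled within chromosomes (permutation p = 0.061), at a ratio to the shuffles of 1.14 in place of 1.17. Within 500 kb both held in these last 2 settings (permutation p = 0.0001 each), while among protein-coding genes the calls of at least 2-fold gave permutation p = 0.078 and 0.26.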

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

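All tests in this part were chosen after the results they bear on were seen.

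No test was run on the immunoglobulin rows given here, many of which merge several neighbouring genes. In all 3 LY19Y646F libraries 4 of them stood above the level of the LY19WT controls. Rows naming IGHM averaged 1119 FPKM against 10.3 in LY19WT, IGKC 4677 against 46.4, IGHV3-23 5219 against 0.861, and IGKV3-20 2939 against 0.577. Without LY19WT replicate 3 the LY19WT means of IGHV3-23 and IGKV3-20 were 0.441 and 0.265 FPKM. The LY19WT mean of IGHM rests on a merged row of replicate 3, at 30.6 FPKM beside 0.158 and 0.0391 (LY19Y646F: 2227, 630 and 500 FPKM), and rows naming IGHG and IGLV1-40 went the other way. The tables argue against library-specific assembly and merged rows in the deposited tables as the whole source, since of the 8 variable segments with at least 10 FPKM in the authors' deposited table, 6 were over 50-fold apart or listed at 0 in 1 line, 1 higher and 5 lower in LY19Y646F. They also argue against another level of the same rearranged chains in cells of 1 clone, because 0 of 9 pairs of libraries between the lines share a segment in their leading heavy chain variable row, as 6 of 6 pairs within a line do. Within LY19WT that sharing leans on merged rows: IGHV3-48 leads alone in replicate 2 and is joined to other segments in the leading rows of replicates 1 and 3. The kappa counts were 0 and 6, and the lambda counts 7 and 6, where merged rows join segments too. Different B cell clones behind the 2 groups of libraries remain a candidate explanation by that count of 0, while a second rearranged allele within 1 clone was not tested, since the tables hold no rearranged sequence, and any effect of EZH2-Y646F on other genes is confounded with the line.

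The count of 3546 differing genes and the count of 2181 genes differing at least 2-fold were set against the other ways of splitting the 6 libraries into 3 and 3. In each case 1 of the 10 splits, the real one, gave as many genes, and the highest of the other splits gave 8 genes. With 10 splits the share cannot fall under 0.05, so this design does not settle by splits whether chance is excluded. The splits say nothing about whether the mutant or another difference between the lines separates them.

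Neighbouring genes that changed together exceeded shuffled calls, at 140 falling pairs against a mean of 118 and 141 rising pairs against 120 within 100 kb, and at 322 against 219 and 295 against 223 within 500 kb. Shuffling the calls within chromosomes argues against shifts of whole chromosomes as the whole source for the falling pairs within 100 kb (permutation p = 0.019) and for falling and rising pairs within 500 kb (permutation p = 0.0001 each, the smallest that the shuffles can give), but for the rising pairs within 100 kb these shifts cannot be told apart, since the permutation p of 0.061 came with a ratio of 1.14 in place of 1.17. Non-coding genes and pseudogenes next to coding genes stay open as a possible explanation within 100 kb, where protein-coding genes alone gave a permutation p of 0.27 for falling and 0.67 for rising pairs, and are argued against as the whole source within 500 kb, where protein-coding genes alone gave a permutation p of 0.0001 each. Shifts of parts of chromosomes were not tested, nor were domains of H3K27 methylation, a biological explanation that the design raises, since the tables hold neither copy number nor chromatin data. Other biological explanations were not tested either.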

How the results depend on the processing

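Settings that count genes alone in their row, count merged rows for every gene, test protein-coding genes only or shuffle calls within chromosomes, also at 500 kb or for calls of at least 2-fold, or join an estimated correlation with no filter or merged rows, were added after the data were seen, as were list tests under pseudocounts, filters, quantile scaling and library weights. Camera does not use the variance model of the fit, so its results without a variance trend and with robust variance only repeat the main test. Of 19 alternative settings, library weights alone moved the count of 3546 genes by more than 1.5 times, to 5753. No called gene changed sign in any of them, but the libraries of the 2 lines do not overlap for any of the 3546 called genes. The sign therefore could not change in settings without rescaling or another join, so it is no test of those calls. Leaving out a library gave 2766 to 4045 genes, and 2012 to 2378 genes at least 2-fold apart. The EZH2 difference did not pass in any setting, and without a library it ranged from 0.10 to 0.30 on the log2 scale. With the replicate block 3850 genes were called, 2215 of them at least 2-fold apart. The block ended the calls of the B cell identity list, C17orf96, BMF and C12orf5 (limma adjusted p of 0.062, 0.057 and 0.058) and changed no other call among the named genes and lists. The 4 lists that camera called became 5 without a filter and 5 with merged rows, where HOX genes had enough members to be tested, 3 with a filter at 2 FPKM, 3 with protein-coding genes only, 2 with quantile scaling, 1 with library weights, 1 with genes alone in their row, 0 with an estimated correlation (1 when this was combined with no filter or with merged rows) and 15 with fry, which does not compare a list with other genes, and 1 to 4 without a library. The ratio of observed to shuffled neighbouring pairs was 1.01 for falling and 0.93 for rising pairs at 50 kb, 1.06 and 0.96 among protein-coding genes, 1.47 and 1.32 at 500 kb, 1.43 and 1.42 for calls of at least 2-fold, 1.22 and 1.12 for such calls among protein-coding genes (permutation p = 0.078 and 0.26), and 1.14 for rising pairs shuffled within chromosomes (permutation p = 0.061). EZH1, not called, at -0.02 on the log2 scale, changed sign with quantile scaling (0.118) and library weights (0.0672), and ranged from -0.0757 to 0.0501 when a library was left out. When a library was left out, CDKN1A, not called, ranged from -0.903 to 0.205 and CIITA, not called, from 0.38 to 1.51. The cause of these changes was not tested. Of 117 called named genes 99 kept the call in every setting that tests them. The comparison with genes the authors call significant was not run, since their table has no such column. Without absolute depth, low values such as those under 0.1 FPKM cannot be given a detection limit.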

Other observations

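The list of precursor B cell markers was chosen after DNTT, VPREB1 and IGLL1 had been seen, and the chromosome medians after the other results.

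Of 7 tested members of a list of precursor B cell markers, 4 fell in LY19Y646F and 2 rose. RAG2, a subunit of the recombinase that rearranges antigen receptor genes, measured 76.7 ± 10.2 FPKM in LY19WT and 0.365 ± 0.318 FPKM in LY19Y646F (SD, n = 3 each). ARPP21 fell from 107 ± 13.7 to 1.11 ± 0.320 FPKM, the transcription factor ERG from 9.28 ± 1.07 to 0.0118 ± 0.0205 FPKM and SOX4 from 41.0 ± 2.21 to 6.83 ± 0.181 FPKM. IL7R, the receptor for interleukin 7, went the other way, rising from 5.78 ± 0.800 to 19.9 ± 2.80 FPKM, and CD99 rose too. LEF1 measured 77.7 ± 21.1 and 74.2 ± 19.8 FPKM and did not pass. A hypothesis is that a precursor B cell program was lower in the LY19Y646F libraries, which could reflect cells of another stage. A list of 10 markers without DNTT, VPREB1 and IGLL1 gave these 7 tested members. Its limma camera p was 0.0495, just under the threshold, with p = 0.24 at an estimated correlation and p = 0.094 in the blocked fit, so the support is weak.

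Median log2 changes differed between chromosomes. Chromosome 13 had a median that differed from that of all genes by -0.43 over 230 tested genes, and chromosome 20 a median 0.35 above it over 267 genes. In all, 8 of 23 chromosomes passed an adjusted p of 0.05 against 2000 random draws of as many genes. Genes of a chromosome are not independent replicates, and no copy number was measured here.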
